A study of Caenorhabditis elegans with 12 samples.

How the data were processed

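RNA of whole adult worms grown at 20 °C on OP50 bacteria was extracted with Trizol and made into libraries with the Illumina TotalScript kit, per the labels' protocols, once with oligo-dT and once with random-hexamer primers for each RNA sample. The 12 libraries were placed in 4 groups of 3 by their titles. In the labels, 2 samples carry a strain name unlike the rest of their genotype and 1 hexamer sample is described as oligo-dT primed, and titles were followed in both cases. The series design says that mRNA was prepared and the molecule label says total RNA, and whether poly(A) RNA was selected is not given in the sources used here. The submitters' processing notes name TopHat, Cufflinks 2.1.1 and Cuffdiff. The genome build and annotation are not given in the sources used here, and of 3873 piRNA genes with a locus of their own 4 had the same start and end as in WBcel235, so coordinates are printed as the files give them and the reference was used for names and RNA classes alone. Of tested genes, 16003 of 16396 with oligo-dT and 9581 of 9855 with hexamers were matched to a class in the WBcel235 gene table.

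The authors deposited, per the file headers, 1 Cuffdiff gene table per priming with an FPKM value for each genotype, a test score, a p-value and a q-value. Each FPKM is the authors' estimate over the libraries of a group, and no replicate spread can be computed from it. A deposited log2 fold column held a spreadsheet error in 1345 rows with oligo-dT and 2548 with hexamers, all with 0 FPKM in fog-2, so log2 folds were recomputed here from both FPKM columns as fog-2 over N2. They differed from the deposited log2 fold by over 0.001 in 5 rows and in 1 row. A further deposited log2 column was sorted on its own, apart from the genes, and was used only against the authors' histogram files, whose bins differed from a recount by at most 1 gene. There were 0 unused columns of per-sample values, and 1 row without a gene name was left out of each table. The authors' table marks 2306 genes as HIDATA with oligo-dT, for loci with too many fragments, at a placeholder of 0 FPKM, and these were not analysed here. Gene models that overlap share a locus in the tables, which held for 31.8% of tested genes with oligo-dT and 34.9% with hexamers.

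Calls are the authors' own: a q-value at or under 0.05 in the deposited table among genes with status OK. No test on read counts was run, because the values are FPKM. Depth is unknown, so no counting interval is given. Where nothing else is stated, p-values of the authors measure the spread between samples that the series design calls biological replicates. The smallest p printed is 5e-05, reached by 129 genes with oligo-dT and 48 with hexamers, and for these the implied standard error, the absolute log2 fold divided by the normal quantile of p, is an upper bound. The test score of the tables was a median of 0.634 (oligo-dT) and 0.604 (hexamers) times that quantile, and so gives other standard errors.

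For 29 gene lists fixed before the data were examined, called against not called genes were compared with all other tested genes by Fisher's exact test, two-sided, per direction, with Benjamini-Hochberg adjustment over lists and directions within a priming. The list of mitochondrial genes had no gene in the tables. The median log2 fold of each list with at least 3 tested genes was set against 10000 random lists of the same size matched on 10 bins of mean FPKM (random seed 1), with p taken as 2 times the smaller tail, called a permutation of list membership, and adjusted over lists; the smallest p it can give is 0.0002. Chromosomes were set against 1000 such lists each, with a smallest p of 0.002. Folds of genes at 0 in 1 group were ranked as 20 or -20. The number of calls adjusted over the list alone applies Benjamini-Hochberg to the authors' p-values within the list. Fisher p-values refer throughout to the authors' calls and not to the numbers adjusted over the list alone. Priming differences were the oligo-dT log2 fold minus the hexamer log2 fold, centred on the median of 8593 genes (-0.06), with a normal test on the combined implied standard errors, taken as independent. As an alternative added after the data were seen, these errors were multiplied by 1 factor, 0.645, that sets the median absolute z over all genes to that of a normal distribution; it assumes that most genes do not differ. Genes tested in lists are not independent replicates. Lists overlap in part: 10 genes are shared by the GLD-1 bound and oocyte lists and 5 by the late embryonic and dosage compensation lists.

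Named genes followed a rule fixed with the lists: fog-2 and the sex-determination list, the 10 called genes with the largest and lowest folds of at least 5 FPKM in 1 group, the 3 called genes per direction listed at 0 in the other group, and up to 4 called members per list with the largest mean FPKM, or the 2 with the smallest q-value. The 10 were taken among genes with a public name. No gene was called for the priming difference, so its part of the rule (8 per sign) named none, and rme-2, gld-1 and tra-2 were added to that test after their values were seen. Alternatives were other q thresholds and adjustments, FPKM minimums of 1 and 5, pseudocounts of 0.1 and 1, centred folds, lists left out and, added after the data were seen, shared loci left out, dosage compensation genes left out of the late embryonic list, and scaled errors. The computations were tested on simulated data drawn with the real errors: with no change put in, 0 of 8593 genes were called for the priming difference, with changes of 1 and 2 on the log2 scale put into 200 genes 5 and 10 other genes were called (6 and 7 with scaled errors, and 0 with no change put in), and the list median and list call tests each found the 1 list that had been shifted by 1 and 0 others among 15892 simulated genes. Genes were drawn independently in these simulations, whereas members of real lists, such as near-identical copies, can vary together. The 0 other lists therefore do not give the rate of false list calls in the real data. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.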

Results

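RNA from adult Caenorhabditis elegans was compared between wild-type N2 hermaphrodites and XX animals of a fog-2(q71) strain, which make no sperm of their own and are labelled as females. FOG-2 is an F-box protein that acts with the RNA-binding protein GLD-1 to allow spermatogenesis in the hermaphrodite germline. The 12 libraries formed 4 groups of 3, since RNA from each animal sample was made into cDNA primed with oligo-dT, which anneals to poly(A) tails, and into cDNA primed with random hexamers, which does not need a tail. The stated aim was to ask whether fog-2 activity affects polyadenylation, by setting the results of both primings against each other. The deposited tables hold 1 pooled FPKM value (fragments scaled to gene model length and to the number of mapped fragments) per genotype for each priming, so values per library, their spread and read depth were not used here. Of 39665 genes in each table, 16396 were tested by the authors with oligo-dT priming and 9855 with random hexamers. The median FPKM of tested genes in N2 was 4.23 with oligo-dT and 26.2 with hexamers.

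The targeted gene itself fell with both primings. In the authors' deposited table for oligo-dT, fog-2 (chromosome V, 20199263 to 20200474, genome build not given in the sources used here) went from 64.2 FPKM in N2 to 14.4 FPKM in fog-2, a log2 fold of -2.16 with q = 0.00636. In the authors' deposited table for random hexamers it went from 34.9 to 7.08 FPKM, a log2 fold of -2.30 with q = 0.0103. The standard errors implied by the authors' p-values were at most 0.53 and 0.57 on the log2 scale, because both p-values were at the smallest value printed. The neighbouring paralog ftr-1 was at 24.8 and 29.5 FPKM with oligo-dT, at a log2 fold of 0.25, and was not called with either priming. Of 26 tested genes of the germline sex-determination list, fog-2 was the only call by the authors with oligo-dT, and of 25 tested with hexamers it was again the only call. The medians of this list were 0.02 and 0.09 (permutation of list membership, adjusted p = 0.247 and 0.541). Adjusted over the list alone, 1 gene was called lower with each priming. The FOG-2 partner gld-1 was at 181 and 155 FPKM with oligo-dT, at a log2 fold of -0.22 with q = 0.743 in the authors' deposited table, and tra-2, a translational target of GLD-1, had a log2 fold of 0.02. The pro-male gene fog-3 had a log2 fold of -1.91 at under 1 FPKM and her-1 one of 1.68, and neither passed the authors' test in the deposited table (q = 0.299 and q = 0.587).

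With oligo-dT priming, the genes called were mostly lower in fog-2 animals and included sperm genes, cuticle genes, C-type lectins and intestinal genes. By q at or under 0.05 in the authors' deposited table, 235 genes were called, of which 180 were lower and 55 higher. By at least 2-fold, 136 were lower and 19 higher. At an unadjusted p under 0.05 the counts were 1025 lower and 360 higher. The median log2 fold of all tested genes was -0.03, and 100 of the genes called lower had at least 5 FPKM in 1 group. Of the called genes, 101 of the lower and 19 of the higher had a public gene name.

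Major sperm protein genes, which encode the cytoskeletal and signalling protein of nematode sperm, were lower in 29 of 29 tested members. Their median log2 fold was -2.42, against a 95% range of -0.30 to 0.04 for random lists matched on expression (permutation of list membership, two-sided, adjusted p = 0.000675). Calls in the authors' deposited table covered 14 of them, all lower (Fisher exact test, two-sided, adjusted p = 8.33e-19), and 22 when adjusted over the list alone. The most abundant called members were msp-36, at a log2 fold of -2.77, msp-76, from 9.09 to 2.51, msp-45, from 9.02 to 1.63, and msp-57, from 8.80 to 1.27. These copies are near-identical, so the value of any single copy is uncertain and the copies are not independent in the list tests. Other sperm genes had a median log2 fold of -1.64 over 31 tested members, 28 of them below 0, and 4 were called lower by the authors, or 9 adjusted over the list alone (Fisher exact adjusted p = 0.00393). The median was below the matched random lists (permutation of list membership, adjusted p = 0.000675). With 1 FPKM added, the medians of major sperm protein genes and other sperm genes shrank to -1.43 and -0.57 and stayed below the random lists (permutation of list membership, adjusted p = 0.000675 for each). The called members were msd-4, from 9.30 to 1.47 FPKM, ssq-1, from 3.11 to 0.983, ssq-2, from 1.71 to 0.149, and nspd-6, which was at 2.38 FPKM in N2 and listed at 0 in fog-2. Male somatic markers, listed to look for males among the animals, had a median of -0.15 over 7 tested of 14 listed members. The list held 0 calls, also when adjusted over the list alone (permutation of list membership, adjusted p = 0.315). Without shared loci that median was 0.28 over 5 members (permutation of list membership, adjusted p = 0.0749). The tested markers were at median levels of 0.526 FPKM in N2 and 0.394 in fog-2, with a random range of -1.30 to 0.18. At such levels the list cannot show whether males were present.

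Genes of the late embryonic and hatching-larva structure list, which includes cuticle and moulting genes and all dpy genes, had a median log2 fold of -0.39 over 34 tested members, and 6 were called lower, or 8 adjusted over the list alone (Fisher exact adjusted p = 4.70e-05). The median lay below the matched random lists (permutation of list membership, adjusted p = 0.00300), a call that was lost with 1 FPKM added to each value, at a median of -0.14. The list shares 5 genes with the dosage compensation list. Without them, an alternative chosen after the data were seen, the median was -0.53 over 30 tested members (permutation of list membership, adjusted p = 0.000600) and 6 were called lower (Fisher exact adjusted p = 2.15e-05). In the authors' deposited table, cut-3, a cuticlin, went from 13.2 to 2.07 FPKM, cut-2 from 11.4 to 2.67, and the collagens sqt-3 and dpy-17 from 25.9 to 10.6 and from 47.2 to 20.3, each with q = 0.00636. Cuticle collagens as a list had 7 members lower and 1 higher among 97 tested, or 12 and 2 adjusted over the list alone (Fisher exact adjusted p = 0.00154 for lower calls), and 4 genes belong to this list and to that of late embryonic and larval structure. The collagen median was -0.28 (permutation of list membership, adjusted p = 0.0418). That call was lost with 0.1 FPKM added, at a median of -0.24 (permutation of list membership, adjusted p = 0.0559). It was also lost without shared loci, at -0.23 over 76 tested (permutation of list membership, adjusted p = 0.132). The call was kept with 1 FPKM added, at -0.15 (permutation of list membership, adjusted p = 0.0112). An FPKM minimum of 1 kept it too, at -0.22 over 53 tested (permutation of list membership, adjusted p = 0.000578). The opposite case was col-143, which rose from 49.1 to 738 FPKM, the largest log2 fold among called genes with a public name and at least 5 FPKM in 1 group (3.91). The largest fall among called genes with a public name by the same rule was in another collagen, col-165, from 11.7 to 1.07 FPKM.

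Genes expressed in the intestine and in defence and fat metabolism were also called lower. Proteases and lipases of the intestine had a median log2 fold of -0.41 over 19 tested members, with 3 called lower and 6 adjusted over the list alone (Fisher exact adjusted p = 0.0103). The median was below the random lists (permutation of list membership, adjusted p = 0.000675). The called genes were the cathepsin B gene cpr-1, from 656 to 355 FPKM, and the lipase genes lipl-2, from 12.8 to 5.46, and lipl-3, from 7.44 to 1.99. Fatty acid synthesis genes had a median of -0.19 over 21 tested, with 3 called lower and 6 adjusted over the list alone (Fisher exact adjusted p = 0.0120). Their median was below the random lists (permutation of list membership, adjusted p = 0.000675), and the called members were the elongases elo-2 and elo-5 and the acetyl-CoA carboxylase pod-2, which fell by 0.69, 0.58 and 0.60 on the log2 scale; elo-5 and pod-2 lie in loci shared with other gene models. C-type lectins had 8 members lower and 1 higher among 133 tested, or 11 and 1 adjusted over the list alone (Fisher exact adjusted p = 0.00154 for lower calls). Their median was -0.31 and missed the threshold (permutation of list membership, adjusted p = 0.0582), as it did with 0.1 FPKM added (-0.27, adjusted p = 0.0660), with an FPKM minimum of 1 (-0.08, 64 tested, adjusted p = 0.0529) and without shared loci (-0.27, adjusted p = 0.122). With 1 FPKM added it was -0.15 and passed (permutation of list membership, adjusted p = 0.00972). Among them clec-190 went from 112 to 24.7 FPKM and clec-47 from 77.9 to 135. Pathogen response genes had 4 members lower and 1 higher among 80 tested, or 6 and 1 adjusted over the list alone, which missed the threshold (Fisher exact adjusted p = 0.0814). Their median of -0.17 lay below the random lists (permutation of list membership, adjusted p = 0.000675), with dod-23 at 1315 and 679 FPKM and spp-2 at 299 and 170 FPKM. Among higher genes, rnh-1.3, named for ribonuclease H, rose from 20.7 to 281 FPKM, msra-1, a methionine sulfoxide reductase, from 341 to 641, and hsp-70, the only call among 19 tested heat shock genes, from 4.55 to 10.4 FPKM. The heat shock list had a median of 0.10 (permutation of list membership, adjusted p = 0.418) and 1 call adjusted over the list alone.

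**Figure D1:**
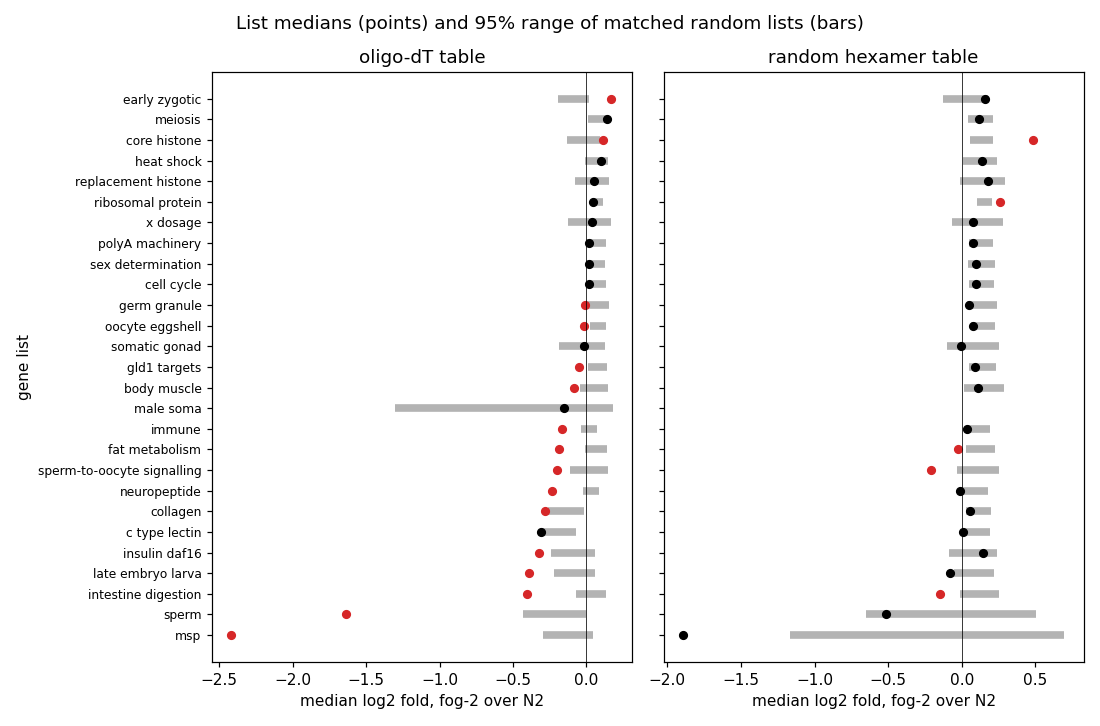
Median log2 fold (fog-2 over N2) of each gene list with oligo-dT priming (left) and random-hexamer priming (right); points are list medians, red where the adjusted p was at or under 0.05, and bars are the 95% range of 10000 random lists matched on expression. Major sperm protein genes lie at -2.42 in the oligo-dT table and core histones at 0.49 in the hexamer table.

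Germline lists other than those of sperm and sex determination held no call with oligo-dT. None of 21 tested mRNAs reported as GLD-1 bound, 31 oocyte and eggshell genes, 26 meiotic genes, 16 germ granule genes, 25 germline cell cycle genes or 25 genes of the poly(A) machinery was called, and the count adjusted over the list alone was 0 in each. Their median log2 folds were -0.05, -0.01, 0.14, -0.01, 0.02 and 0.02. The GLD-1 bound, oocyte and germ granule medians lay below those of random lists of the same expression (permutation of list membership, adjusted p = 0.000675, 0.00594 and 0.0418), while the meiotic, cell cycle and poly(A) lists missed the threshold (adjusted p = 0.0565, 0.0665 and 0.259). The 0 calls stand beside 1385 tested genes with an unadjusted p under 0.05. Early zygotic genes, which are transcribed in embryos, had a median of 0.17 over 64 tested members with 0 calls, above the random lists (permutation of list membership, adjusted p = 0.000675). Neuropeptides (-0.23, 65 tested), insulin-like peptides and DAF-16 regulated genes (-0.32, 36 tested), genes of sperm-to-oocyte signalling (-0.20, 14 tested) and body wall muscle genes (-0.09, 14 tested) lay below the random lists with 0 calls each (permutation of list membership, adjusted p = 0.000675, 0.0126, 0.0113 and 0.0150). Without shared loci the call of the signalling list was lost (6 genes, permutation of list membership, adjusted p = 0.0679). Core histones had a median of 0.12 over 28 tested with 0 calls, above the random lists (permutation of list membership, adjusted p = 0.0305), a call that was lost with 1 FPKM added (0.07, adjusted p = 0.137) and without shared loci (0.08, adjusted p = 0.254). With an FPKM minimum of 1 the median was again 0.12, over 24 genes, and missed the threshold (permutation of list membership, adjusted p = 0.0529). Replacement histones (0.05, 13 tested), ribosomal protein genes (0.04, 64 tested), somatic gonad genes (-0.02, 16 tested) and dosage compensation genes (0.04, 10 tested) did not pass adjustment (permutation of list membership, adjusted p = 0.877, 0.0926, 0.914 and 0.974), with 0 calls each. The 0 calls of the lists in this paragraph were also 0 adjusted over the list alone. Of the vitellogenins, only vit-1 was tested with oligo-dT, at 1047 and 1126 FPKM, and 4 others carried the authors' mark for loci with too many fragments.

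With random-hexamer priming, 81 genes were called and RNAs without poly(A) tails were among those higher in fog-2. By q at or under 0.05 in the authors' deposited table, 53 were higher and 28 lower, and at an unadjusted p under 0.05 the counts were 628 higher and 256 lower. The median log2 fold of all tested genes was 0.10. With folds centred on that median the split turned to 31 higher and 62 lower, so the majority of higher calls depended on the scaling of the table. The share of lower calls was 34.6% as deposited and 66.7% with centred folds. The smallest q in this table was 0.0103, so no gene could pass a threshold of 0.01. The series design speaks of mRNA and the sample labels of total RNA, and whether poly(A) RNA was selected before priming is not given in the sources used here.

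Core histone mRNAs of the replication-dependent clusters, which end in a stem-loop and not in a poly(A) tail, had a median log2 fold of 0.49 over 31 tested members, or 0.38 relative to the median of all tested genes. The 95% range of matched random lists was 0.05 to 0.21 (permutation of list membership, adjusted p = 0.00180). Without shared loci the median shrank to 0.34 over 26 genes and stayed above the random lists (permutation of list membership, adjusted p = 0.00500). Higher calls in the authors' deposited table numbered 3 (Fisher exact adjusted p = 0.00801), and 13 higher and 3 lower when adjusted over the list alone. The called members were his-67, from 1380 to 2099 FPKM, his-5, from 135 to 229, and his-55, from 46.3 to 138. Core histone copies share sequence, so values of single copies are uncertain and the copies are not independent in the list tests. The ribosomal RNA gene rrn-2.1 went from 4431 to 25019 FPKM, and rrn-1.1 was listed at 0 in N2 and at 169 FPKM in fog-2. The snRNA-class gene sup-6, in a locus of 4 gene models, went from 368 to 1325 FPKM, and mrpr-1, named for the RNA of RNase MRP, from 294 to 990 FPKM. Ribosomal protein genes had a median of 0.26 over 76 tested with 0 calls, above the random lists (permutation of list membership, adjusted p = 0.00180).

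Several genes of the cuticle and lectin lists were called with hexamers too. By the authors' deposited table, cut-3, sqt-3 and mlt-11 were the 3 members called lower among 25 tested late embryonic and larval structure genes (Fisher exact adjusted p = 0.00245), with 5 lower and 1 higher adjusted over the list alone. Of these, cut-3 went from 9.21 to 2.22 FPKM. Among 44 collagens 3 were lower and 2 higher, or 4 and 3 adjusted over the list alone (Fisher exact adjusted p = 0.00624 for lower calls), with col-135 at 27.8 and 9.11 FPKM and col-143 at 24.6 and 545 FPKM. Of 49 C-type lectins, clec-190, clec-222 and clec-223 were lower, with 5 lower and 2 higher adjusted over the list alone (Fisher exact adjusted p = 0.00624). The alcohol dehydrogenase gene sodh-1 went from 163 to 49.8 FPKM. Of 49 pathogen response genes dod-23 was lower and dod-19 higher, or 2 and 1 adjusted over the list alone. The medians of intestinal proteases and lipases (-0.15, 18 tested), fatty acid genes (-0.03, 23 tested) and sperm-to-oocyte signalling genes (-0.21, 13 tested) lay below the random lists (permutation of list membership, adjusted p = 0.00216, 0.00216 and 0.00180) with 0 calls, or 5, 0 and 0 lower adjusted over the list alone. Without genes in shared loci the fatty acid and signalling medians turned to 0.022 (16 genes) and 0.055 (5 genes) and lost their calls (adjusted p = 0.200 and 0.645 by permutation of list membership). The late embryonic and larval, collagen, C-type lectin and pathogen response medians were -0.08, 0.06, 0.01 and 0.04 and did not pass (permutation of list membership, adjusted p = 0.106, 0.394, 0.171 and 0.124). Without dosage compensation genes the late embryonic and larval list held 3 lower calls among 20 tested (Fisher exact adjusted p = 0.00122), at a median of -0.17 (permutation of list membership, adjusted p = 0.0522).

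Sperm genes were largely untested with hexamers. Of 30 major sperm protein genes listed, 5 were tested with hexamers, with a median log2 fold of -1.90, 5 of 5 below 0 and 0 called, and the list's adjusted p by permutation of list membership was 0.0999. Other sperm genes had a median of -0.52 over 5 tested members, 3 below and 2 above 0 (permutation of list membership, adjusted p = 0.199). No male somatic marker was tested. The lists not yet named held 0 calls with hexamers, and their medians did not pass adjustment. These were mRNAs reported as GLD-1 bound (0.09, 25 tested), oocyte and eggshell genes (0.08, 34 tested), early zygotic genes (0.16, 36 tested), vitellogenins (0.04, 5 tested), meiotic genes (0.12, 28 tested), germ granule genes (0.05, 18 tested), cell cycle genes (0.10, 28 tested), replacement histones (0.18, 11 tested), the poly(A) machinery (0.08, 28 tested), heat shock genes (0.14, 18 tested), insulin-like and DAF-16 genes (0.14, 19 tested), neuropeptides (-0.01, 58 tested), somatic gonad genes (-0.01, 14 tested), body wall muscle genes (0.11, 15 tested) and dosage compensation genes (0.07, 11 tested). Adjusted over the list alone, 1 gene was higher in each of the replacement histone, heat shock and dosage compensation lists and 0 in the others, against 884 genes with an unadjusted p under 0.05 in the whole table.

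Fold changes with both primings went the same way for nearly all oligo-dT calls that were also tested with hexamers. Among 8675 genes tested in both tables, 27 were called lower in both, where 0.307 would be expected from independent lists, and 12 were called higher in both, where 0.282 would be expected. No gene was called in opposite directions. Of 144 oligo-dT calls tested with hexamers, 142 had the same sign there, and of 78 hexamer calls 60 had the same sign with oligo-dT. A further 91 oligo-dT calls were not tested with hexamers, so their direction there is not known. Genes called in both included fog-2, cut-3, sqt-3, clec-190, col-143, rnh-1.3 and msra-1. Across 8593 genes with values above 0 in all 4 groups, Pearson's r of the log2 folds was 0.48 and Spearman's rho 0.41, and among the 182 genes of these called with at least 1 priming r was 0.82. Genes are not independent replicates, and the same RNA samples were used for both primings, so chance differences between samples are shared by both tables.

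**Figure D2:**
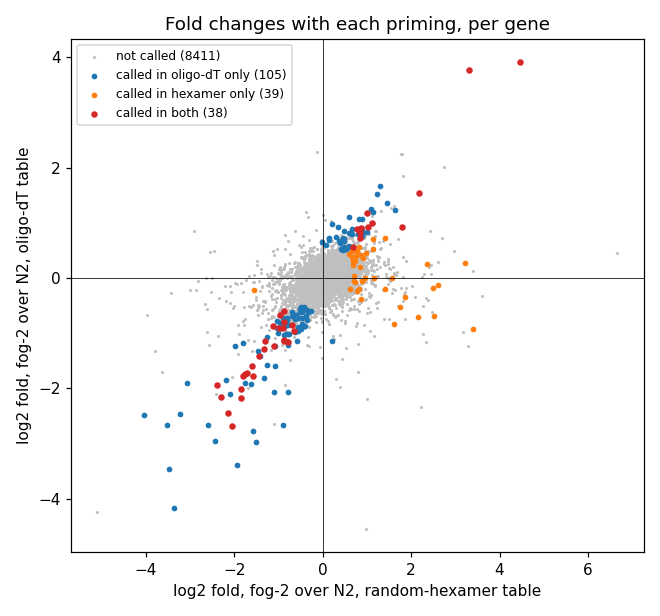
Log2 fold (fog-2 over N2) of each of 8593 genes in the random-hexamer table (horizontal) and in the oligo-dT table (vertical); red points were called by the authors in both tables, blue in the oligo-dT table only, orange in the hexamer table only and grey in neither. The highest red point is col-143, at 4.47 and 3.91, and several orange points lie above 1 on the horizontal axis and near or below 0 on the vertical axis.

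The question of the design, whether the fold between genotypes differed between primings, was tested per gene on the difference of the log2 folds. With standard errors implied by the authors' p-values, 0 of 8593 genes passed (normal test, two-sided, Benjamini-Hochberg), and 138 (1.61%) had an unadjusted p under 0.05. This test takes the errors of both primings as independent, although each RNA sample was primed both ways, and 1.61% is below the share that chance gives at this threshold. With all standard errors multiplied by 0.645 to match the spread over all genes, an alternative added after the data were seen, 58 genes passed, 44 of them with a lower fold with oligo-dT and 14 with a higher one. Of genes that the naming rule had picked in other comparisons they included rrn-2.1, sup-6, mau-8, elc-1 and his-67, all with a lower fold with oligo-dT, and uig-1, with a higher one. They did not include fog-2, gld-1, tra-2 or rme-2. The number of genes with a priming difference thus depended on the error used. With standard errors taken from the authors' test statistic, 29 genes passed, 24 of them with a lower fold with oligo-dT than with hexamers. The difference, oligo-dT minus hexamer and relative to the median of all genes, was 0.20 for fog-2 with a standard error of 0.78, -0.19 ± 0.22 (SE) for gld-1, -0.01 ± 0.27 (SE) for tra-2 and -0.26 ± 0.23 (SE) for the yolk receptor gene rme-2, another GLD-1 target. In simulated tables with independent errors, the test recovered 82.0% of 200 genes changed by 2 on the log2 scale and 41.5% of 200 changed by 1. With scaled errors, in tables simulated at that spread, it recovered 86.5% and 68.0%.

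By list, the GLD-1 bound mRNAs had a median difference of -0.04 over 21 genes (permutation of list membership, adjusted p = 0.986), the sex-determination genes 0.01 over 24 (adjusted p = 0.937) and the poly(A) machinery -0.03 over 24 (adjusted p = 0.858). Core histones (-0.21, 27 genes), ribosomal protein genes (-0.16, 63 genes) and neuropeptides (-0.18, 52 genes) had a fold that was lower with oligo-dT than with hexamers (permutation of list membership, adjusted p = 0.00173 for each). The other lists did not pass adjustment. This permutation compares lists of genes in pooled values and does not measure the spread between RNA samples.

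The ratio of oligo-dT to hexamer FPKM was lowest for core histones in both genotypes. Relative to the median of all genes, core histones were at -6.76 on the log2 scale in N2 and at -6.97 in fog-2, over 27 genes. Ribosomal protein genes were at 0.74 and 0.59, GLD-1 bound mRNAs at -0.60 and -0.70 and the poly(A) machinery at -1.03 and -1.04. The tables were normalized separately, so these levels are described without a test.

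**Figure D3:**
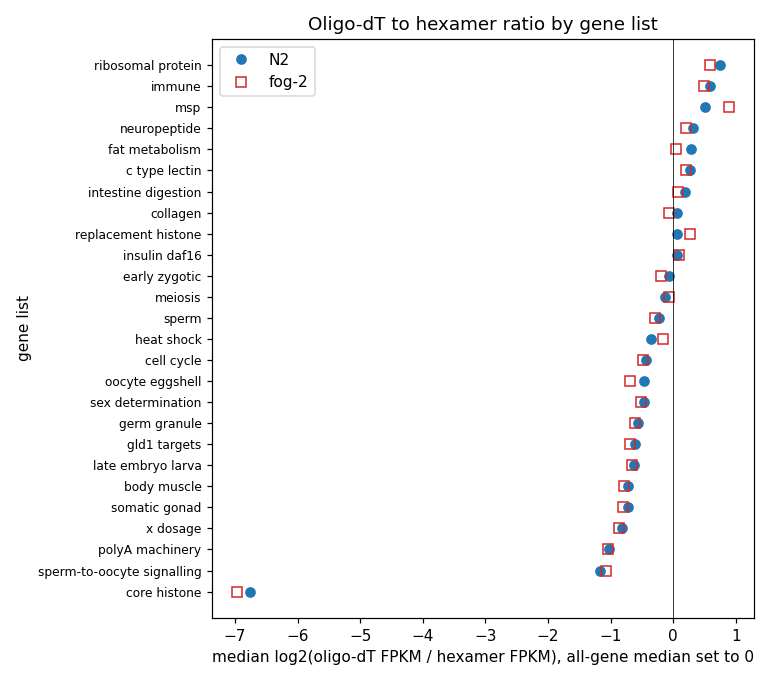
Median log2 ratio of oligo-dT to random-hexamer FPKM for each gene list, with the median of all genes set to 0; circles are N2 and open squares fog-2. Core histones lie at -6.76 in N2 and -6.97 in fog-2, apart from all other lists.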

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

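The tests of explanations in this part were chosen after the results were seen; the list comparison itself was planned. In 3 gene lists the median priming difference lay below that of matched random lists, by permutation of list membership. These were core histones (-0.21), ribosomal protein genes (-0.16) and neuropeptides (-0.18), each as oligo-dT minus hexamer log2 fold relative to all genes. The permutation compares genes in pooled values and does not measure the spread between RNA samples. For ribosomal protein genes and neuropeptides no explanation was tested.

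For core histones, the higher level in fog-2 with hexamers was weighed together with other RNAs without a poly(A) tail. An overall scaling of the hexamer table would move all genes alike, so it does not account for the gap between core histones and matched random lists. The core histone median was 0.38 above the median of all tested genes, which restates the planned list result and is not a further test. More carry-over of non-polyadenylated RNA in the fog-2 hexamer libraries may account for part of it but was left undecided, also because it is not known whether the input was mRNA or total RNA: relative to all genes snoRNAs (31 tested), snRNAs (10 tested) and lncRNAs (5 tested) had medians of 2.07, 2.14 and 1.29 and both tested rRNAs were called higher, while the ncRNA class (181 tested) was at -0.61 and miRNAs (5 tested) at -0.60, with the tail status of lncRNA, ncRNA and miRNA members not known here. This test was first run on snoRNAs and snRNAs alone and then widened to all noncoding classes with at least 5 tested genes, after which the classes went both ways. The ncRNA class held 5 higher and 1 lower hexamer calls. With oligo-dT it was low too, at -0.71 relative to all genes (1056 tested), so its fall was not particular to hexamers. There snoRNAs and snRNAs were at -0.09 and -0.32 (28 and 16 tested), without the rise seen with hexamers. A higher level of core histone mRNA in fog-2 animals stays open, because the oligo-dT median of 0.12 goes the same way but is small, in a priming that sees these RNAs poorly.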

How the results depend on the processing

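Leaving out shared loci, leaving dosage compensation genes out of the late embryonic list and scaled errors were chosen after the data were seen; other alternatives were planned. No paired analysis was possible because the tables hold 1 pooled value per genotype, and leaving out each replicate and the replicate block were not run for the same reason. At q 0.01 the oligo-dT calls were 23 higher and 106 lower, while hexamer calls were 0 and 0, hexamer list calls 0 and the overlap 0, since the smallest hexamer q is 0.0103. At an unadjusted p under 0.05 they were 360 higher and 1025 lower with oligo-dT and 628 and 256 with hexamers. With an absolute log2 fold of at least 1, higher calls were 19 with oligo-dT, hexamer calls 26 higher and 18 lower, and the overlap 20. With 5 FPKM in 1 group, lower oligo-dT calls were 100. Centring the folds gave 31 higher and 62 lower hexamer calls, by its construction from the shift of 0.10. Without shared loci, 3 hexamer list medians passed in place of 5: those of fatty acid and sperm-to-oocyte signalling genes reversed to 0.022 and 0.055. Uncalled medians that changed sign there were those of male somatic markers (0.28) and somatic gonad genes (0.024) with oligo-dT and of neuropeptides (0.063) and somatic gonad genes (0.00073) with hexamers; the cause was not tested. The correlation was 0.82 among called genes, which are chosen for large folds. Errors from the test statistic gave 29 priming differences in place of 0, and errors scaled to the spread of all genes gave 58; the cause of the former was not tested, and the latter multiplies every error by 0.645. With 1 FPKM added, the core histone priming ratio was -6.13 in place of -6.76. Over the lists with a random-list test, 174 of 188 comparisons of a list median with its alternative kept direction and side of the threshold, 7 kept direction and lost the call, 6 reversed and 1 gained a call; these include the late embryonic list without dosage compensation genes, with which list calls stayed at 7 with oligo-dT and 4 with hexamers. Other counts of calls stayed within 1.5 times; an FPKM minimum of 1 removed no tested hexamer gene and so tests nothing there, and its 27 hexamer comparisons are left out of the 188. Depth is unknown and limits which genes could be tested.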

Other observations

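The tests of explanations in this part were chosen after the results were seen. Chromosomes differed slightly in their median fold with oligo-dT: genes on the X chromosome had a median log2 fold of -0.13 over 2858 tested genes and those on chromosome V one of -0.11 over 3922, both below 1000 random lists matched on expression (permutation of list membership, adjusted p = 0.00400 for each, from an unadjusted 0.002 that is the smallest 1000 lists can give), while chromosomes II and III lay above them at -0.01 and 0.03 (adjusted p = 0.00400 and 0.0480). With hexamers the X median was 0.03 against 0.10 for all tested genes (permutation of list membership, adjusted p = 0.0120) and that of chromosome III 0.13, above its random lists (adjusted p = 0.0180). Chromosome III held 13 oligo-dT calls among 2204 tested genes, a lower share than elsewhere (Fisher exact adjusted p = 0.000627), and chromosomes IV and V a higher one (49 of 2393 and 73 of 3922, Fisher exact adjusted p = 0.0267 and 0.0269). With hexamers chromosome V held 25 calls among 1718 tested genes, a higher share too (Fisher exact adjusted p = 0.0173). These Fisher tests take genes as independent, which near-identical copies such as the msp genes are not.

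Sperm gene transcripts were lower in fog-2 with oligo-dT. Movement of reads between near-identical msp copies is argued against, since the sum over all 30 copies fell too. It went from 154 to 35.8 FPKM, or to 23.3% (bootstrap interval over copies 19.6% to 28.2%). Bootstrap intervals in this part resample genes, since values per library were not at hand, and do not measure the spread between samples. Low expression is also argued against, as the lowest of 10000 matched random lists had a median of -0.64 against -2.42. The fog-2 females make no sperm of their own, which is the difference that the design names. Whether this accounts for the fall cannot be told apart from other effects of genotype here. That 95% of 60 tested msp and sperm genes were below 0 restates the pattern and adds no support. Whether the fall extends beyond multigene families cannot be told apart from chance here, since 10 single-copy sperm genes had a median of -0.81 with a bootstrap interval of -1.27 to -0.20, inside the range of matched lists. With hexamers only 2 single-copy sperm genes were tested, both above 0 at a median of 0.37.

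Cuticle and moulting genes were lower in fog-2 with oligo-dT. Early zygotic genes, taken as a marker of early embryos carried by N2 hermaphrodites, were not lower (median 0.17, bootstrap interval over genes 0.05 to 0.22). The list was at a median of 3.48 FPKM in N2, and nothing here shows that it detects embryos in whole adults. Early embryos therefore could not be excluded as the source, and late embryos were left untested. A difference in age after the last moult stays open, since the labels give no age within the adult stage: families of moulting genes had a median of -0.44 over 100 tested, below the random range of -0.37 to -0.11, with 11 called lower and 2 higher. With hexamers their median was -0.22 over 26 tested (bootstrap interval -0.51 to 0.10), below the random range of -0.19 to 0.21 too, with 1 lower call. The unadjusted p by permutation of list membership was 0.00640 with oligo-dT and 0.0286 with hexamers. Lower values of moulting families restate the pattern and add no support for a difference in age.

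A hypothesis that variants linked to the q71 allele may raise calls near fog-2 was left undecided: 5 of 242 tested genes within 1 Mb were called against 229 of 16153 elsewhere (Fisher exact p = 0.401, odds ratio 1.47, 95% interval 0.467 to 3.52). These shares are 2.07% and 1.42%, and the rest of chromosome V, which is part of the latter, was at 1.82% (67 of 3679). Genes in loci shared by 5 or more gene models were called in 6 of 2727 cases with oligo-dT against 200 of 11185 with a locus of their own, at median implied standard errors of 0.883 and 0.253.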
